A study of Homo sapiens with 48 samples.

How the data were processed

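The series holds bulk RNA-seq of NCI-H358, an established human lung cancer epithelial cell line that carries a mutant KRAS and lacks TP53, per the labels. Cells carried barcodes of the Oligo-CALL system, which marks lineages and allows clones of a chosen barcode to be isolated from a mixed population. Clones of the same barcode were isolated from a treatment-naive and from an AMG510-resistant population, giving 3 matched clone pairs, here clone 1, clone 2 and clone 3. The unsorted naive and resistant populations, here the pool, formed the fourth lineage. AMG510 (sotorasib) is a covalent inhibitor of one mutant form of KRAS. Each of the 8 cultures was treated with 2 µM AMG510 or vehicle for 3 days, in 3 biological replicates, which made 16 groups and 48 libraries. Each group was taken from the sample's title. The design text spells the barcode of resistant clone 2 differently from the sample labels, and the labels were followed. The replicates of a group are named biological, and nothing in the labels says how the cultures were separated, so p-values measure the spread between these cultures of a clone.

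Libraries were made from total RNA with the NEBNext Ultra RNA kit, per the labels' protocols. Alignment with STAR, the tool DESeq2 and the genome build hg38 are named without versions or roles in the submitters' processing notes. The program that assigned reads to genes, its gene annotation, any filter on genes and the use of strand are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The deposited table gives a signal per gene and library, with 22392 genes by Ensembl ID, and no header states its unit. Tested on the file, the deposited signal behaved as an estimated count divided by 1 factor per library. In each library the low values were whole multiples of a step between 0.43 and 2.42, and the median ratio to the genes' geometric means lay between 1.005 and 1.023, the scale that a median-of-ratios factor gives. Within a tolerance of 0.01 of a whole read, 46.1% to 68.2% of the values above 0 in a library were whole, so reads had been shared out between genes by estimation and whole reads could not be recovered for most genes. The values are called normalised read counts below. Dividing by each library's step gave estimated depths of 6203563 to 35954542 reads per library. The shallowest library was a naive pool library in vehicle, which had 3341 genes at 0 against at most 1357 in any other library. None of the 1128 pairs of libraries held identical values.

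The test planned before the data were examined assumed unnormalised counts. Because the table holds normalised estimates, a test on the log scale was used in its place, and the pseudocount, the filter and the test were therefore chosen after the table had been seen. Values were transformed to log2(value + 8). Genes with a value of at least 10 in at least 3 libraries were kept, which left 20396. A linear model with 16 group means was fitted to all 48 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend in the prior variance), without a term for the replicate number. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison. A gene was called changed at an adjusted p below 0.05 with an absolute log2 fold change of at least 1 (2-fold). A fold change on the log2(value + 8) scale understates the change of low genes. Means and SDs are of normalised read counts over 3 libraries. Standard errors (SE) come from the shared spread, so they are equal across lineages for a gene and contrast type.

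In each lineage 5 comparisons were made, 20 in all: AMG510 against vehicle in naive cells, the same in resistant cells, resistant against naive cells in vehicle, the same in AMG510, and the interaction, which is the AMG510 effect in resistant cells minus that in naive cells. For 4 of these, the 3 clones were also treated as replicates. The log2 difference of each clone was the unit, so such a test asks for a change that exceeds the spread between clones. Genes with the same difference in all 3 clones were given a p of 1 there, a handling chosen after a first fit. An F test compared the 3 clones of a state in vehicle (9 libraries), with the spread taken from the fit to all 48 libraries. The pool signature was the set of genes called in the naive pool with AMG510, measured in the other lineages and states. The resemblance of siblings was the mean correlation across genes of the 3 differences between naive clones with the matching differences between resistant clones, set beside the 5 other assignments of barcodes.

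The 31 gene lists were written from textbook knowledge before the data were examined. They cover RAS-ERK output, receptor tyrosine kinases (RTKs) and ligands, RAS and RAF-MEK-ERK genes, S phase and E2F, G2-M and mitosis, CDK inhibitors and p53 targets, mesenchymal, epithelial, YAP-TEAD targets, TGF-beta and BMP targets, alveolar, airway secretory and ciliated, squamous, neuroendocrine, type I interferon response, MHC class I and II, NF-kB and cytokines, cholesterol synthesis, fatty acid synthesis and desaturation, glycolysis and hypoxia, NRF2 targets, ATF4 and unfolded protein response, ribosome biogenesis, apoptosis regulators, drug efflux and aldehyde dehydrogenases, Wnt and Notch targets, FOXO and PI3K feedback, mitochondrially encoded, cytosolic ribosomal protein, replication-dependent histone, and fibroblast, endothelial and immune marker genes. Each list was tested against all other genes with camera (limma, preset inter-gene correlation of 0.01), adjusted over the 31 lists of a comparison. Of 620 such tests 269 passed, against 123 with an estimated correlation, 492 with fry and 265 with a block for the replicate number. The text says that a list was higher or lower where camera passed, and that a member rose or fell at an adjusted p below 0.05, with no minimum fold. Where a camera call was lost with an estimated correlation, that p is given.

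Genes named in the text followed a rule set before the data were examined. For each family of comparisons except resistant against naive in AMG510 it takes up to 8 genes per direction that passed in all 4 lineages, ranked by their smallest fold change, and per lineage the 3 called genes per direction with the largest fold change and no overlap between replicates, among genes with at least 5 CPM in the higher group. Up to 4 members with the smallest adjusted p are taken from each list described, over the 4 lineages or in the lineage the sentence names. KRAS, TP53, DUSP6, MKI67, VIM and CDH1 are always taken. Unnamed loci were passed over. Coordinates are those of GENCODE release 29 on GRCh38 (hg38), 1-based, for 21224 of the gene IDs, and symbols come from a table that held 22203 of them.

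The fit, the contrasts, camera and the test across clones were run on simulated libraries, with 200 genes of a mean of at least 50 changed. These were drawn from the real genes' means over all groups and their spread between cultures. Recovery and false calls were counted at an adjusted p below 0.05 in limma, with no minimum fold. For AMG510 in naive clone 1 the test recovered 49, 48, 49 and 50 of 50 genes changed by log2 -2, -1, 1 and 2, with 5 false calls among 20396 genes. For the interaction in clone 1 it recovered 48, 44, 43 and 50 of 50 at 2, 1, -1 and -2. For a change shared by 3 clones it recovered 200 of 200, with 22 false calls. The simulated clones had the same means and the same added change, without the real spread between clones. This recovery therefore does not show how many shared changes the test would find in the real clones. Simulated changes of log2 -1 and 1 had median estimates of -0.97 and 0.98 in naive clone 1, and -0.98 and 0.97 for the interaction. These medians lie short of 2-fold, so the 2-fold rule would call fewer of those genes than were recovered. The alternatives tried were other scalings (median of ratios recomputed, TMM, total sum), filters, pseudocounts of 1 and 32, no minimum fold, a test against a log2 fold change of 0.5, voom on the estimated reads, a fit of each lineage alone, a block for the replicate number, each clone left out and each replicate left out. Every deposited column and row was used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.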

Results

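RNA was sequenced from 4 lineages of NCI-H358 lung cancer cells, 3 barcoded clones and the pool they came from. Each lineage was present as a treatment-naive and as an AMG510-resistant culture, and each culture received vehicle or AMG510 for 3 days. The 16 groups held 3 libraries each. The normalised read counts of a library summed to between 13504184 and 16822496, and the estimated depth lay between 6203563 and 35954542 reads. All values below are means ± SD over 3 libraries unless stated. The genome build is hg38, and fold changes are log2 values with standard errors from limma.

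The transcript of the drug's target and that of the lost tumour suppressor were read first. KRAS (ENSG00000133703, chromosome 12, 25204789 to 25250936) was present in every group, at 2282.7 ± 122.9 normalised read counts in the naive pool with vehicle. TP53 (ENSG00000141510, chromosome 17, 7661779 to 7687550), which encodes the p53 protein that this line lacks, had group means between 23.8 and 82.2 except for 243.4 ± 10.6 in the naive pool with AMG510.

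AMG510 locks mutant KRAS in its inactive form, so its direct effect on transcription runs through the RAS-ERK cascade, which carries growth signals to the nucleus. The first comparison asked what 3 days of the drug did to cells that had not been selected for resistance. In all 4 lineages the transcripts that ERK signalling drives fell, those of DNA replication and mitosis fell with them, and the epithelial gene CDH1 and targets of the antioxidant factor NRF2 rose. In clone 1, clone 2, clone 3 and the pool, 1933, 1576, 1664 and 2217 genes changed at least 2-fold in limma. Of these, 849, 624, 668 and 1046 rose and 1084, 952, 996 and 1171 fell. Without the minimum fold the balance turned, with 5153, 4675, 4482 and 5527 that rose and 4742, 4477, 4206 and 4843 that fell. The lineages shared 181 genes that rose and 395 that fell, where independent lists would share 0.044 and 0.142. Bulk libraries of the pool cannot tell a response within cells from a change in the mixture of cells during treatment.

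**Figure D1:**
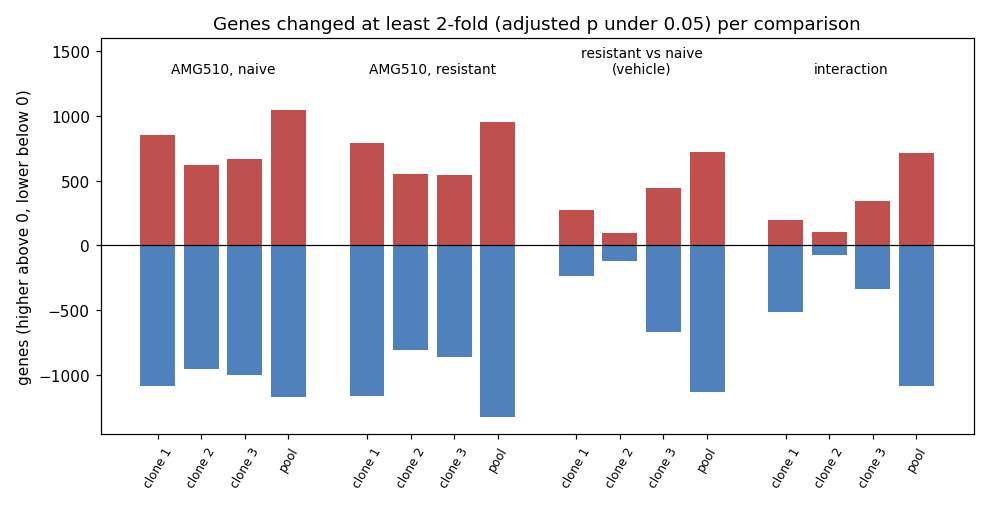
Number of genes changed at least 2-fold at an adjusted p below 0.05 in each lineage and comparison, with genes that rose above 0 (red) and genes that fell below 0 (blue). AMG510 in the naive pool changed the most genes among the naive lineages (1046 higher, 1171 lower), and resistant against naive clone 2 the fewest of that comparison (98 higher, 123 lower).

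Feedback inhibitors that ERK signalling induces to restrain itself fell in all 4 naive lineages. DUSP6 (ENSG00000139318, chromosome 12, 89347232 to 89353271), a phosphatase that switches ERK off, went from 490.3 ± 17.7 to 32.5 ± 1.9 normalised read counts in naive clone 1 and from 849 ± 67.5 to 14.2 ± 1.7 in the naive pool. Its log2 fold changes were -3.62, -4.44, -5.42 and -5.27 (SE 0.16 each) in clone 1, clone 2, clone 3 and the pool. SPRY4, which blocks receptor signals upstream of RAS, had log2 fold changes of -3.08, -3.76, -4.00 and -4.47. The ETS factors ETV1, ETV4 and ETV5, transcription factors that carry out part of the ERK programme, fell too, ETV5 with -3.37, -3.58, -3.36 and -4.33. DUSP4, a nuclear ERK phosphatase, had -4.32, -4.47, -2.98 and -0.78. Of the 28 genes of RAS-ERK output, 24, 22, 24 and 24 fell in clone 1, clone 2, clone 3 and the pool, with the same counts adjusted over the list alone, and the list medians were -1.49, -1.40, -1.60 and -1.75. The members with the smallest adjusted p in limma over the 4 lineages were ETV5, PHLDA1, FOSL1 and DUSP6. PHLDA1 encodes an ERK-induced regulator of survival and FOSL1 a subunit of the AP-1 transcription factor.

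Genes of other functions fell too. VCAN, a large matrix proteoglycan, had log2 fold changes between -3.42 and -4.04, and COL13A1, a membrane collagen, between -3.01 and -4.06. IL11, a cytokine that ERK and TGF-beta induce, fell from 609.9 ± 18 to 15.1 ± 2.9 normalised read counts in clone 1. ADGRF5, an adhesion receptor of lung and vessel cells, fell from 496.1 ± 14.5 to 5.7 ± 4.1 in clone 3. TNFRSF6B, a decoy receptor whose gene overlaps RTEL1, fell from 371.5 ± 49.3 to 0.1 ± 0.1 in clone 3 and was listed at 0 in all 3 naive pool libraries with AMG510. VIM (ENSG00000026025, chromosome 10, 17228259 to 17237593), the intermediate filament of mesenchymal cells, fell by 1.22, 0.85, 0.89 and 1.61 in clone 1, clone 2, clone 3 and the pool. The mesenchymal list as a whole was lower in the pool, where 15 of 24 genes fell and 6 rose (15 and 6 adjusted over the list alone; median -0.78). FN1, TNC, VIM and CDH11 led it there, encoding fibronectin, tenascin, vimentin and a mesenchymal cadherin.

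The transcripts of cycling cells fell as well. MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126385), a marker of cycling cells, fell from 2889.6 ± 96.8 to 579.4 ± 71.4 normalised read counts in naive clone 1. CKAP2L, which helps to build the mitotic spindle, fell by 2.57, 2.87, 2.59 and 2.52 on the log2 scale in the 4 lineages. All 30 genes of G2-M and mitosis fell in every naive lineage (30 of 30 adjusted over the list alone), with medians of -2.06, -2.45, -1.84 and -1.98. TOP2A, TPX2, UBE2C and CENPF led the list, encoding a topoisomerase, a spindle factor, a ubiquitin-conjugating enzyme of mitotic exit and a kinetochore protein. Of the 30 genes of S phase and E2F, 30, 29, 29 and 27 fell (the same adjusted over the list alone; medians -2.06, -2.03, -1.50 and -1.59), led by TYMS and TK1, enzymes of thymidine supply, and MCM4 and MCM6, subunits of the replicative helicase.

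PTGDS, which makes prostaglandin D2, ranked first by its smallest fold change among the genes that rose in all 4 naive lineages. It rose by 4.68, 4.26, 4.11 and 3.56 on the log2 scale, and reached 9896 ± 469.1 normalised read counts in clone 1. SECTM1, a secreted immune ligand, DPEP1, a membrane dipeptidase, DIO2, which activates thyroid hormone, and PSG1, a secreted pregnancy glycoprotein that shares reads with its gene family, rose at least 2.74 in each lineage. ALDH1A3 and ALDH1A1, which make retinoic acid, rose as well, ALDH1A1 from 10 ± 2.7 to 681.6 ± 120.9 in clone 1. In clone 1 COL4A4, a chain of basement membrane collagen, rose from 3.4 ± 3.1 to 280.8 ± 31.7. AMTN, an enamel matrix protein, and SLC34A2, the phosphate carrier of alveolar cells, rose in all 4 lineages, AMTN by 4.52, 4.74, 0.63 and 4.27 and SLC34A2 by 3.61, 4.33, 0.92 and 4.85, the latter from 6.9 ± 0.8 to 427 ± 66.9 in the pool. EDN2, a vasoconstrictor peptide, rose by 4.92 in clone 3 and by 4.75 in the pool.

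The epithelial list was higher in clone 3 and the pool, and did not pass in camera in clone 1 and clone 2 (medians 0.26 and 0.32). CDH1 (ENSG00000039068, chromosome 16, 68737225 to 68835548), the adhesion protein of epithelial junctions, rose by 2.67, 1.99, 3.17 and 2.03 on the log2 scale in clone 1, clone 2, clone 3 and the pool, and from 962.1 ± 67 to 3946.6 ± 163.3 normalised read counts in the pool. KRT19, a keratin of simple epithelia, rose from 150.6 ± 23.2 to 7320.4 ± 521.7 in clone 3. In clone 3, 19 of 24 epithelial genes rose (20 adjusted over the list alone; median 1.01), and in the pool 21 did (21 adjusted over the list alone; median 1.17), led by CDH1, ELF3 and KRT19. ELF3 encodes an epithelial ETS factor.

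The antioxidant response moved with them. HMOX1, which degrades haem, rose by 3.80, 3.41, 4.25 and 2.74 on the log2 scale. Of 25 targets of NRF2, the factor that induces antioxidant enzymes, 20, 18, 19 and 25 rose in clone 1, clone 2, clone 3 and the pool (20, 19, 19 and 25 adjusted over the list alone), with medians of 1.03, 0.53, 0.52 and 1.11. TXNRD1, HMOX1, G6PD and FTL led the list, supplying reduced thioredoxin, haem breakdown, NADPH and iron storage. The type I interferon response was lower in clone 3 and the pool, where 17 and 21 of 30 genes fell (17 and 21 adjusted over the list alone; medians -0.53 and -0.67). In the pool IFITM1, IFITM3, HERC5 and IFIT1 led it, genes that restrict viruses. In the 4 naive lineages 13, 13, 13 and 12 of 13 mitochondrially encoded genes rose (the same adjusted over the list alone; medians 0.59, 0.78, 0.71 and 0.64). That camera call was lost with an estimated correlation, at adjusted p = 0.28, 0.197, 0.23 and 0.228 with an estimated correlation.

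**Figure D2:**
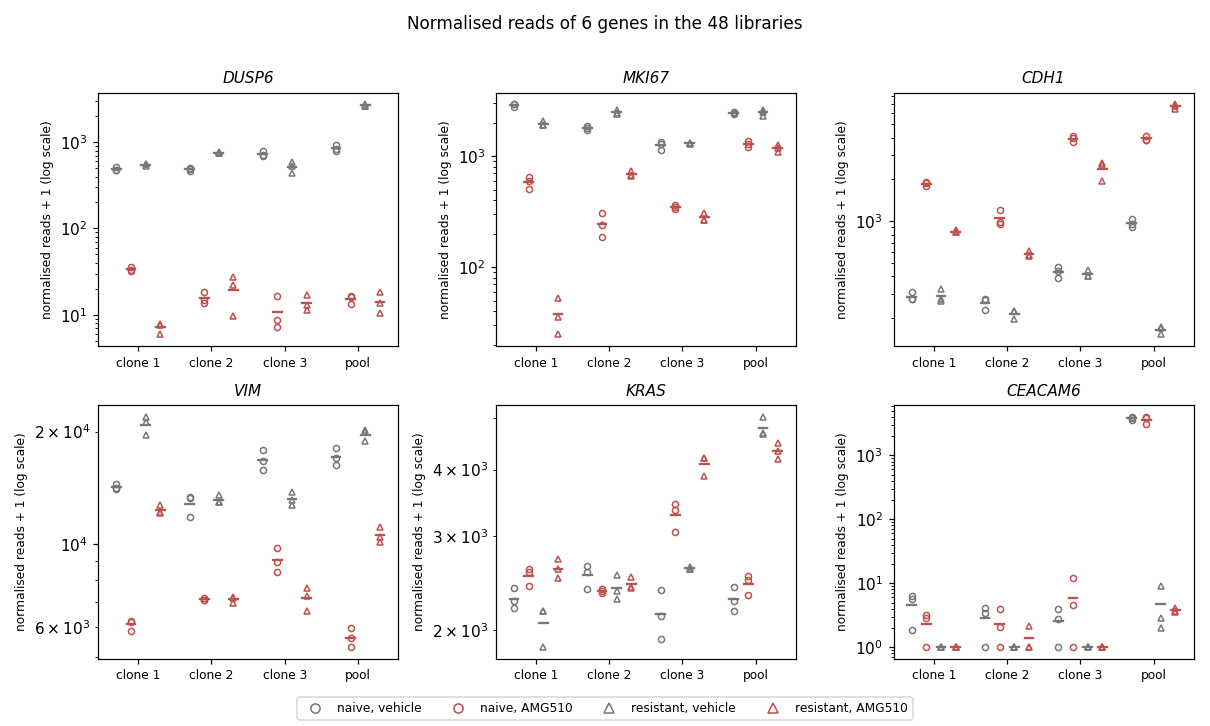
Normalised read counts plus 1 (log axis) of 6 genes in each of the 48 libraries, by lineage on the horizontal axis, with circles for naive and triangles for resistant cultures, grey for vehicle, red for AMG510 and a bar at each group's mean. DUSP6 fell with AMG510 in all 8 cultures, MKI67 fell to 36.6 in resistant clone 1, and CEACAM6 had 3776 in the naive pool with vehicle.

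The next comparison asked whether cells selected for resistance still answered AMG510. In resistant clone 1, clone 2, clone 3 and the pool, 1950, 1355, 1404 and 2277 genes changed at least 2-fold in limma. Of these, 787, 547, 541 and 955 rose and 1163, 808, 863 and 1322 fell, and without the minimum fold 5150, 4463, 4478 and 5289 rose and 4566, 4022, 3675 and 5261 fell. ERK targets and cell cycle genes fell again. The lineages shared 140 genes that rose and 371 that fell, where independent lists would share 0.026 and 0.126. Across genes, the log2 fold changes in resistant cells correlated with those in naive cells with Pearson r of 0.789, 0.822, 0.723 and 0.609 in clone 1, clone 2, clone 3 and the pool, over genes that are not independent replicates. Of the genes called in naive cells, 96.8%, 98.3%, 94.8% and 85.9% moved in the same direction.

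DUSP6, SPRY4, ETV4, ETV1, DUSP4 and FOSL1 ranked first, by their smallest fold change, among the genes that fell in all 4 resistant lineages. DUSP6 fell from 545.9 ± 14.3 to 6.1 ± 1.1 normalised read counts in resistant clone 1 and from 2679.7 ± 78.2 to 13.1 ± 3.8 in the resistant pool, with log2 fold changes of -5.29, -4.90, -4.67 and -7.01 (SE 0.16 each). FOSL1 fell by 4.37, 3.21, 2.88 and 3.81 on the log2 scale. COL13A1 had log2 fold changes between -2.87 and -5.27, and ARHGAP26, which turns off the small GTPase RHOA, between -2.66 and -3.93. Of the 28 genes of RAS-ERK output, 25, 23, 26 and 26 fell (the same adjusted over the list alone; medians -2.72, -1.49, -2.08 and -2.80), led by FOSL1, PHLDA1, DUSP6 and SPRY4. NT5E, an enzyme that makes adenosine outside the cell, fell from 9789.2 ± 452.2 to 144.6 ± 12.5 in resistant clone 3. SLCO4A1, a carrier of organic anions, fell from 1525 ± 35.6 to 13.8 ± 6.2 in the resistant pool.

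The cell cycle genes fell in every resistant lineage, and furthest in clone 1. TOP2A fell from 8318.2 ± 217.9 to 161.8 ± 6.1 normalised read counts and MKI67 from 1961.6 ± 101.2 to 36.6 ± 14 in resistant clone 1. All 30 genes of G2-M and mitosis fell in every resistant lineage (30 of 30 adjusted over the list alone; medians -4.44, -2.11, -2.10 and -1.72), led by TPX2, CCNB2, TOP2A and CCNB1, of which CCNB1 and CCNB2 encode the cyclins of mitotic entry. Of the 30 genes of S phase and E2F, 30, 29, 29 and 27 fell (the same adjusted over the list alone; medians -2.79, -1.67, -1.34 and -0.92), led by TYMS, MCM7, MCM4 and MCM3.

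Among the genes that rose in all 4 resistant lineages, COL3A1, a fibrillar collagen, ranked first by its smallest fold change. It rose by 4.76, 3.53 and 3.89 on the log2 scale in clone 1, clone 2 and clone 3, rose in the pool too, and reached 1762.7 ± 116.2 normalised read counts in resistant clone 1. NPR3, which clears natriuretic peptides, GASK1B, a Golgi protein whose reads are partly shared with other genes, ABI3BP, a matrix protein, CRYAB, a small heat shock protein, EDN2, SECTM1 and the metalloproteinase MMP24, whose reads are shared, rose in all 4 lineages, NPR3 by 3.33 to 4.08. ALDH1A1, COL4A4 and PTGDS rose in resistant clone 2 as they had in naive clone 2. SLC27A2, which activates fatty acids, rose from 56.8 ± 4.4 to 1484.5 ± 37.7 and the gap junction gene GJA1 from 8.2 ± 1.7 to 338.3 ± 57.6 in resistant clone 3. In the resistant pool CCN5, a secreted inhibitor of growth, rose from 8.2 ± 3.4 to 1010.9 ± 63, and the placental phosphatase ALPP, which shares reads with ALPG, rose by 6.12. CDH1 rose by 1.53, 1.41, 2.47 and 5.30, and VIM fell by 0.76, 0.88, 0.88 and 0.89 in clone 1, clone 2, clone 3 and the pool.

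Of 25 NRF2 targets 21, 16, 18 and 10 rose with AMG510 in resistant clone 1, clone 2, clone 3 and the pool (the same adjusted over the list alone; medians 1.00, 0.36, 0.58 and 0.11). The list was higher in the 3 clones in camera but lost that call in clone 2, at adjusted p = 0.102 with an estimated correlation, and camera gave adjusted p = 0.2 in the pool. The interferon response was lower in the resistant pool, where 23 of 30 genes fell (24 adjusted over the list alone; median -1.17), led by IFITM1, HERC5, IFIT2 and OASL. NF-kB and cytokine genes fell there too, 20 of 24 (21 adjusted over the list alone; median -1.02), led by ICAM1, IL32, LTB and CSF2, with IL32, a proinflammatory cytokine, the one of these that rose. The ATF4 list, genes of amino acid supply and protein folding stress, was lower in the resistant pool, with 19 of 25 genes falling (19 adjusted over the list alone; median -1.01), led by the serine pathway genes PSAT1, MTHFD2, SHMT2 and PHGDH. Mitochondrially encoded genes rose, 13, 13, 13 and 8 of 13 (the same adjusted over the list alone), at adjusted p = 0.246, 0.138, 0.204 and 0.642 with an estimated correlation in camera.

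The third comparison asked what distinguished resistant from naive cells after 3 days of vehicle. The sample titles do not say whether the resistant cells had been kept in AMG510 until then. Most of the genes that differed in a lineage were not shared by all 4, and the lists that moved differed between lineages. In clone 1, clone 2, clone 3 and the pool, 508, 221, 1111 and 1846 genes differed at least 2-fold in limma, 275, 98, 442 and 717 higher and 233, 123, 669 and 1129 lower in resistant cells. With total-sum scaling, 232, 111, 487 and 919 were higher and 289, 111, 609 and 996 lower, which turned the balance in clone 1. All 4 lineages shared 3 genes that were higher and 7 that were lower, where independent lists would share 0.001 and 0.003. The 3 higher ones were PRAME, PDZD2, a scaffold protein, and ZNF641, a zinc finger factor, the latter 2 chosen after their values were seen. With the clones as replicates limma called 0 genes, with 1303 of 20396 at an unadjusted p below 0.05. With no change in any gene, a share of about 0.05 would fall below that p. An average of the 3 clones' contrasts, which carries the spread between cultures and not between clones, called 192.

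The genes that moved the same way in all 4 lineages came from different functions. PRAME, a cancer-testis antigen that represses retinoic acid signalling, was higher in resistant cells by 1.53, 1.54, 2.35 and 2.35 on the log2 scale in clone 1, clone 2, clone 3 and the pool. ITPR1, a calcium channel of the endoplasmic reticulum, PCLO and MCTP1, proteins of vesicle release, RRAGD, which signals amino acids to mTORC1, KLK6, a secreted protease, and the epithelial factor KLF4 were higher as well. DUSP5, a nuclear ERK phosphatase, was higher by 0.85, 0.79, 0.63 and 2.07. H19, an imprinted long noncoding RNA, had log2 fold changes of -1.45, -1.77, -5.40 and -3.35. ANPEP, a surface aminopeptidase, TENM2, an adhesion protein, PYGM, which breaks down glycogen, SERPINF1, a secreted inhibitor of vessel growth, PSD4, an exchange factor of ARF6, FERMT3, an integrin activator, and IFITM1, whose reads are shared with its neighbours, were lower in all lineages.

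Clone 1 differed in cholesterol synthesis and cell cycle genes. Of 24 genes of cholesterol synthesis 18 were lower in resistant clone 1 (18 adjusted over the list alone; median -0.56), led by DHCR24, FDPS, INSIG1 and STARD4, which make, regulate and carry sterols. Of 30 genes of S phase and E2F 28 were lower (28 adjusted over the list alone; median -0.59). G2-M genes were lower too, 27 of 30 (29 adjusted over the list alone; median -0.51), a camera call lost at adjusted p = 0.128 with an estimated correlation. TGF-beta and BMP targets were higher, 13 of 19 (13 adjusted over the list alone; median 0.38), led by TGFB1, SERPINE1, SMAD7 and ID1. DNAH6, a motor of cilia, rose from 79.4 ± 2.4 to 1777 ± 24.4 normalised read counts, LCP1, an actin bundler of blood cells, from 32.5 ± 3 to 451.2 ± 15.6, and TIE1, a receptor of vessel cells, from 66.4 ± 1.1 to 721.5 ± 85.1. TM4SF18, a membrane protein, ALDH3A1, an aldehyde dehydrogenase, and CCDC8, a p53 cofactor, were lower, with log2 fold changes of -3.38, -3.29 and -3.02. Mitochondrially encoded genes were higher, 10 of 13 (10 adjusted over the list alone), at adjusted p = 0.202 with an estimated correlation in camera.

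Clone 2 moved the other way on the cell cycle. There 20 of 30 genes of S phase and 25 of 30 of G2-M were higher in resistant cells (21 and 27 adjusted over the list alone; medians 0.30 and 0.44). Of the 3 naive libraries in vehicle 1 differed more from each of the others than these did from each other, and without it 16 and 22 genes were higher, with medians of 0.28 and 0.42 and adjusted p = 0.0319 and 0.0488 with an estimated correlation in camera. Mesenchymal genes were lower, 10 of 24 (11 adjusted over the list alone; median -0.14), led by FN1, TGFBI, SPARC and COL6A1, which encode matrix proteins. ARLNC1, a long noncoding RNA whose reads are shared with other genes, TSPAN7, a membrane protein, and MAGEA11, a cancer-testis antigen, were higher by 3.30, 3.06 and 2.93 on the log2 scale. NPFFR2, a neuropeptide receptor, VEGFC, which drives lymphatic growth, and KIRREL1, an adhesion protein, were lower, VEGFC from 102.7 ± 19.6 to 4.6 ± 1.4 normalised read counts. Mitochondrially encoded genes were lower in 10 of 13 (12 adjusted over the list alone), at adjusted p = 0.138 with an estimated correlation in camera.

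Clone 3 differed most among the clones, and in antigen presentation. Of 21 MHC class I and II genes 16 were higher in resistant clone 3 (16 adjusted over the list alone; median 0.64), led by HLA-B, HLA-DPA1, HLA-C and B2M, the chains of the molecules that present peptides. Reads of HLA genes are shared between family members. TACSTD2, an epithelial surface protein, rose from 63 ± 21 to 2509.4 ± 236 normalised read counts, and PREX1, an exchange factor of RAC, from 95.6 ± 8.7 to 1632.9 ± 50.1. SLC1A3, a glutamate carrier, was listed at 0 in all 3 naive libraries with vehicle and had 151.7 ± 11.3 in the resistant ones. ALPG, a placental phosphatase that shares reads with ALPP, MMP2, which digests matrix, and MEDAG, an adipogenic factor, were lower, MMP2 from 1541.1 ± 35.1 to 26.4 ± 3.2. Replication-dependent histones were lower in 7 of 10 (7 adjusted over the list alone; median -0.69), led by H1-2, H2AC6, H4C8 and H2BC5. Mitochondrially encoded genes were lower in 9 of 13 (9 adjusted over the list alone; median -0.30), at adjusted p = 0.807 with an estimated correlation in camera.

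Airway and epithelial genes were lower in the resistant than in the naive pool. These bulk libraries cannot tell a change within cells from a change in the mixture of cells. CEACAM6, an adhesion protein of airway epithelium, went from 3776 ± 213.2 normalised read counts in the naive pool to 3.7 ± 4 in the resistant pool, and ALDH3A1 from 2659.9 ± 19.1 to 4.6 ± 4. S100A9, a calcium-binding protein of inflammation, went from 1614.4 ± 14.3 to 0.3 ± 0.6. Of 13 airway secretory and ciliated genes 12 were lower (12 adjusted over the list alone; median -4.63), led by ALDH3A1, CEACAM5, CEACAM6 and MUC5AC, the last a mucin. Epithelial genes fell with them, 19 of 24 (19 adjusted over the list alone; median -1.55), led by ELF3, CDH1, KRT19 and EPCAM. Squamous genes were lower in 11 of 15 (11 adjusted over the list alone; median -0.94), led by the keratins KRT17 and KRT6A. NF-kB genes and NRF2 targets were lower in 20 of 24 and 20 of 25 (20 and 20 adjusted over the list alone; medians -1.24 and -0.80), and the aldo-keto reductases AKR1B10, AKR1C2 and AKR1C1, which share reads, led the latter.

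Stress and growth transcripts were higher in the resistant than in the naive pool, with the same limit. KRAS had 4788.5 ± 200.5 normalised read counts in the resistant pool against 2282.7 ± 122.9 in the naive pool, a log2 fold change of 1.07 (SE 0.06, adjusted p = 5.65e-20 in limma), against -0.15, -0.08 and 0.29 in clone 1, clone 2 and clone 3. Its neighbours BCAT1 and ETFRF1, the latter overlapping KRAS in its annotated position, were higher by 1.02 and 1.00, and both were chosen after their values were seen. Of 28 genes of RAS-ERK output 19 were higher (19 adjusted over the list alone; median 0.62). The ATF4 list was higher in 18 of 25 (18 adjusted over the list alone; median 1.20), led by PSAT1, MTHFD2, ASNS and ATF4 itself. Ribosome biogenesis was higher in 20 of 28 (21 adjusted over the list alone; median 0.32). CHAC1, which degrades glutathione, rose from 43.4 ± 10.5 to 919.9 ± 29.7, the esterase BCHE from 2.7 ± 2.6 to 150.8 ± 12.4, and the vessel peptide gene APLN from 15.9 ± 7.5 to 260.3 ± 14.6.

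With AMG510 present, 1093, 315, 1041 and 1874 genes differed between resistant and naive cells in clone 1, clone 2, clone 3 and the pool in limma. In clone 1 all 30 G2-M genes were lower in resistant cells with the drug (30 adjusted over the list alone; median -2.75), whereas in clone 2 29 of 30 were higher (29 adjusted over the list alone; median 0.76). In the pool 25 of 25 NRF2 targets were lower (25 adjusted over the list alone; median -1.57).

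The interaction asked directly whether the effect of AMG510 differed between resistant and naive cells. In limma, 710, 177, 680 and 1798 genes differed at least 2-fold in clone 1, clone 2, clone 3 and the pool, 200, 106, 345 and 716 upwards and 510, 71, 335 and 1082 downwards. The counts were 338, 52, 321 and 880 with a pseudocount of 32, and 489, 25, 423 and 1451 in a test against a log2 fold change of 0.5. With the clones as replicates limma called 0 genes, with 1118 of 20396 at an unadjusted p below 0.05, where a share of about 0.05 would fall by chance. The average of the contrasts called 97. All 4 lineages shared 1 gene in each direction, where independent lists would share 0.001 and 0.002. These were MEDAG upwards and FOSB, an AP-1 subunit, downwards, chosen after their values were seen. MEDAG had at most 3.9 normalised read counts on average in any resistant group.

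Some genes moved the same way in every lineage. The response of L1CAM, an adhesion protein, was higher in resistant cells by 0.69, 0.87, 1.14 and 1.77 on the log2 scale. The responses of MYLK3, a myosin kinase, HOOK1, a cargo adaptor, PALMD, a cytoskeletal protein, SERPINF1 and TPCN1, a lysosomal channel, were higher too, as were those of SYNM and DCHS2, whose reads are shared. ALDH1A3, FOS, DUSP5, CDCP1, FOSL1, SERPINE1 and LUM fell further or rose less in resistant cells, FOSL1 with interactions of -1.40, -1.10, -0.82 and -0.64. FOS encodes an AP-1 subunit, CDCP1 a receptor of SRC signals, SERPINE1 an inhibitor of plasminogen activation and LUM a matrix proteoglycan. FBXO32, a ubiquitin ligase of muscle wasting, moved with them.

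In clone 1 the fall of cell cycle and ERK genes was deeper in resistant cells. The interaction of MKI67 was -3.20 (adjusted p = 2.29e-19 in limma) and that of TOP2A -3.60. All 30 G2-M genes fell further (30 adjusted over the list alone; median -2.26), led by TOP2A, UBE2C, BIRC5 and DLGAP5, and so did 25 of 30 S phase genes (25 adjusted over the list alone; median -0.82). Of 28 genes of RAS-ERK output 24 fell further (24 adjusted over the list alone; median -1.10), led by CCND1, IER3, PHLDA1 and EPHA2, and DUSP6 fell further by 1.67. Of 12 markers of fibroblasts, endothelium and immune cells 5 fell further (6 adjusted over the list alone; median -0.55). Cholesterol synthesis went the other way, 18 of 24 (18 adjusted over the list alone; median 0.60), led by SREBF2, LDLR, STARD4 and SC5D. MAP1LC3C, an autophagy protein, LCN10, a lipocalin, and AQP7, a glycerol channel, rose more in resistant than in naive clone 1, MAP1LC3C from 10.4 ± 3.4 to 121.4 ± 14.2 normalised read counts. KIF4A, a mitotic motor whose reads are shared, and DHRS3, a retinal reductase, fell further or rose less.

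All 11 lists that camera called in clone 2 and all 12 in clone 3 lost that call with an estimated correlation, where the smallest adjusted p was 0.103 and 0.0661. In clone 2 the largest interactions were those of IGFN1, a muscle protein whose naive libraries with vehicle varied widely (310.1 ± 203.6 normalised read counts), and of NPIPB13 and NOTCH2NLB, whose reads are shared, upwards, and of KRT19, SPANXB1, whose reads are shared, and AMTN downwards. In clone 3 CLDN2, a tight junction protein, fell from 206.7 ± 11.3 to 0.9 ± 1.5 in naive cells, against 8.2 ± 2.8 to 0.3 ± 0.5 in resistant cells. MEDAG fell in naive clone 3 from 452.7 ± 33.6 to 20.2 ± 4.4 and had 2.6 ± 0.8 in resistant clone 3 with vehicle, where it was listed at 0 in all 3 libraries with AMG510. CLIC5, a chloride channel, fell in naive and rose in resistant clone 3, from 420.4 ± 22.6 to 125.8 ± 15.3 against 54.2 ± 2.1 to 202.6 ± 0.5. RAB7B, a trafficking GTPase, EGR3, an early growth response factor, and LDLRAD1, a membrane protein, moved downwards.

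In the pool the antioxidant and amino acid lists had interactions. Here too, the bulk libraries cannot tell a change within cells from a change in the mixture of cells. Of 22 genes that were under 10 normalised read counts in every clone group and at least 100 in the naive pool with vehicle, 16 rose with AMG510 in the naive pool and 20 were under 10 in the resistant pool with vehicle. SLC7A11, which imports cystine, rose from 535.1 ± 20.1 to 1448.1 ± 85 normalised read counts in naive and fell from 1267.9 ± 156.8 to 90.6 ± 22.7 in resistant cells, an interaction of -5.14 (SE 0.19, adjusted p = 3.41e-25 in limma). Of 25 NRF2 targets 21 rose less or fell further (21 adjusted over the list alone; median -0.84), led by SLC7A11, TXN, ME1 and GCLM, and 17 of 25 ATF4 genes did (17 adjusted over the list alone; median -1.01), led by PSAT1, DDIT4, ATF4 and MTHFD2. Of 28 genes of RAS-ERK output 19 had a higher start in the resistant than in the naive pool, in vehicle. With AMG510 the list fell further, 19 of 28 (20 adjusted over the list alone, median -1.18), led by DUSP4, CCND1, MYC and IER2. S phase genes went the other way, 19 of 30 (20 adjusted over the list alone; median 0.61). Mesenchymal genes rose more or fell less, 16 of 24 (17 adjusted over the list alone; median 0.59), led by FN1, SPARC, CDH11 and COL1A1. CDH1 had an interaction of 3.27. KRT17 was 24.2 ± 9.1 in resistant cells with vehicle and 1817.2 ± 77.6 with AMG510, and SLC34A2 no longer rose, with 33.8 ± 2.6 and 22.2 ± 3.4. SLCO2A1, a prostaglandin carrier, and LYPD6B, a membrane protein, had interactions upwards, and both fell with AMG510 in naive cells.

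**Figure D3:**
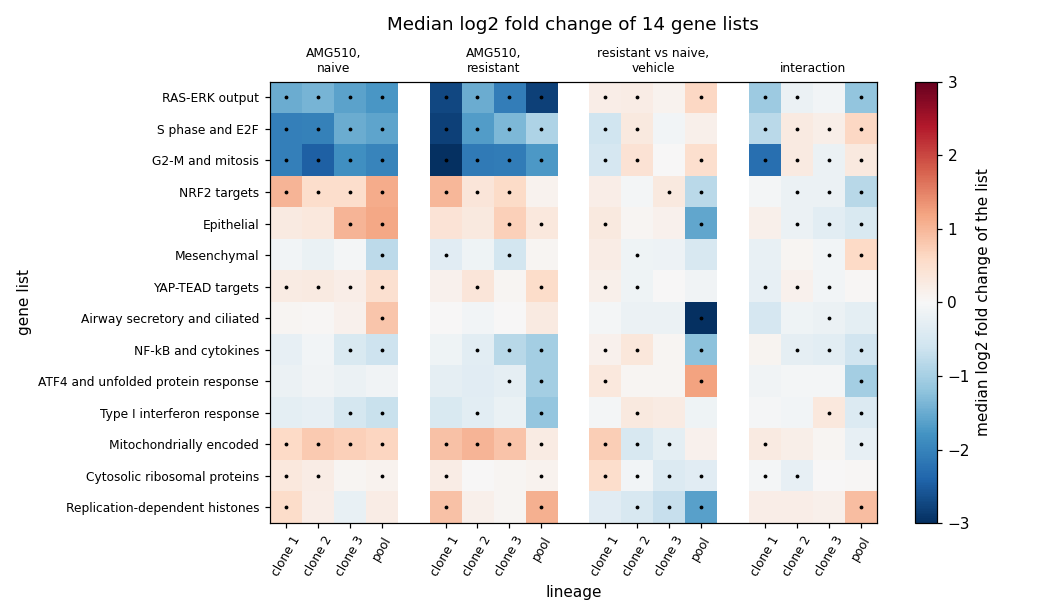
Median log2 fold change of 14 gene lists (vertical axis) in each lineage (horizontal axis) for 4 comparisons, on a colour scale that stops at -3 and 3, with a dot where camera gave an adjusted p below 0.05. RAS-ERK output fell with AMG510 in all 8 cultures, and the airway list had a median of -4.63 between the resistant and the naive pool.

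A further set of comparisons asked which changes exceeded the spread between clones and how clones differed from each other. Across the 3 naive clones AMG510 changed 1226 genes at least 2-fold in limma with the clones as replicates (456 higher, 770 lower), and across the 3 resistant clones 1112 (378 higher, 734 lower). Between the clones of a state in vehicle, 2947 genes differed at least 2-fold among naive and 4006 among resistant clones, and 1778 were in both lists, where independent lists would share 578.8. Clone 3 stood apart in 2458 of the naive and 2574 of the resistant differences. Across genes, which are not independent replicates, differences between naive clones correlated with the matching differences between resistant clones at a mean Pearson r of 0.524 for siblings of the same barcode. The 5 other assignments of barcodes gave -0.36 to 0.291. They reuse the same differences, so they are not an independent reference. For siblings, r was 0.304 for clone 1 minus clone 2, 0.555 for clone 1 minus clone 3 and 0.714 for clone 2 minus clone 3. With resistant clone 1 and clone 2 exchanged, these were -0.304, 0.664 and 0.513, so the mean rested largely on clone 3.

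The pool signature, genes that AMG510 raised (1046) or lowered (1171) in the naive pool, was then read in the other cultures. Genes that rose in the naive pool had median log2 fold changes of 0.706, 0.539 and 0.687 in naive clone 1, clone 2 and clone 3, and of 0.605, 0.517, 0.527 and 0.644 in resistant clone 1, clone 2, clone 3 and the pool. Genes that fell had medians of -1.138, -0.934 and -1.106 in naive clones and of -1.212, -0.941, -0.991 and -1.139 in resistant clone 1, clone 2, clone 3 and the pool. Between resistant and naive clones in vehicle the medians were 0.047, -0.012 and 0.048 for the first set and -0.192, 0.144 and -0.112 for the second. In camera the first set gave unadjusted p = 0.114, 0.185 and 0.215 in clone 1, clone 2 and clone 3. The second set was lower in clone 1 and clone 3 and higher in clone 2, at unadjusted p = 0.00356, 0.00646 and 0.00145 in camera.

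**Figure D4:**
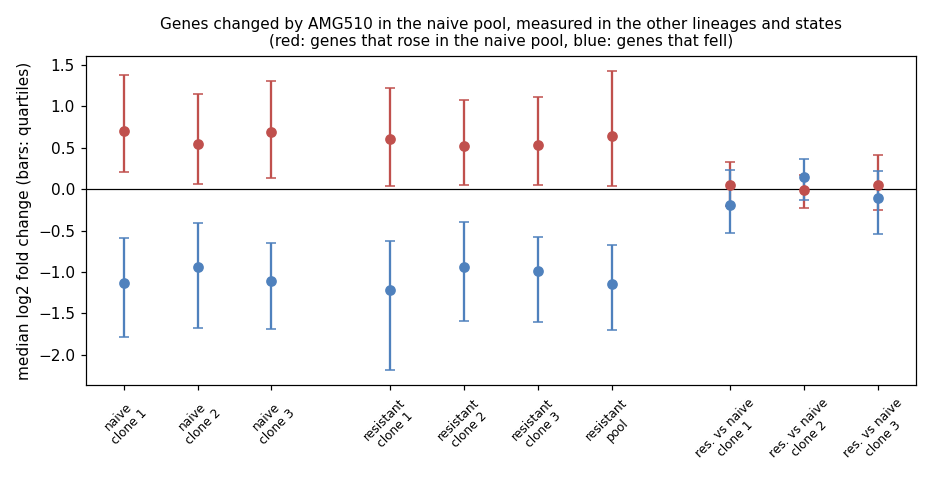
Median log2 fold change (dots) with quartiles (bars) of the genes that rose (red) or fell (blue) with AMG510 in the naive pool, measured in the other cultures and between resistant and naive clones in vehicle. AMG510 moved both sets in the same directions in all 7 other cultures, and between resistant and naive clones their medians lay between -0.192 and 0.144.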

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

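The tests of explanations and the counts over regrouped libraries in this part were chosen after the results they measure had been seen.

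The effect of AMG510 differed between resistant and naive cells, by the interaction itself, for 710, 177, 680 and 1798 genes in clone 1, clone 2, clone 3 and the pool. Lists were taken where camera passed with both correlations, fry passed and the median interaction was at least 0.5 in size. In clone 1 these medians were -1.1 for RAS-ERK output, -0.82 for S phase and E2F, -2.26 for G2-M and mitosis, 0.6 for cholesterol synthesis and -0.55 for fibroblast, endothelial and immune markers. The last list was written for cells of other kinds, and PDGFRB, LUM, KDR and DCN led it. In the pool the medians were -1.18 for RAS-ERK output, 0.61 for S phase and E2F, 0.59 for mesenchymal, 0.71 for alveolar, -0.58 for NF-kB, -0.84 for NRF2 targets, -1.01 for ATF4 and 0.93 for replication-dependent histones.

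Here and in the next paragraph, splits of libraries were fitted to the regrouped libraries alone. The counts of the real groups therefore differ from those of the fit to 48 libraries. For the interaction, splits regrouped the labels naive and resistant within each treatment. Counting the real grouping, at least as many genes were called in 8 of 100 splits for clone 1 (real 737, highest other 3435), 9 of 100 for clone 2 (162; 1262), 13 of 100 for clone 3 (654; 3840) and 2 of 100 for the pool (1600; 1726). Splits that called several times the real count point to the structure of the samples: where resistant and naive libraries are mixed to a different extent in vehicle and in AMG510, the difference between them enters the contrast. These splits therefore decide nothing about chance for the interaction. For the differences among clones 1 of 100 splits, the real one, gave as many genes. The real and highest other counts were 2933 and 2338 in naive cells, and 4023 and 2558 in resistant cells. Cultures of a clone thus resembled each other more than those of other clones. With 1 clone per barcode and state, the splits cannot tell whether the differences go with the barcode or arose by chance between isolates.

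With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real groups gave 1936, 1555, 1650 and 2114 genes for AMG510 in naive clone 1, clone 2, clone 3 and the pool, 1954, 1356, 1403 and 2273 in resistant cells, 510, 209, 1094 and 1741 between resistant and naive cells in vehicle, and 1090, 314, 1035 and 1873 in AMG510. The highest other split gave 0 in each, and 1 of 10 splits, the real one, gave as many. With the 3 clones as replicates there are 4 assignments of signs, too few as well: AMG510 gave 1226 and 1112 genes in 1 of 4 (highest other 0), and resistance and the interaction gave 0 in 4 of 4 (highest other 0).

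KRAS was higher in the resistant than in the naive pool by 1.07 on the log2 scale. More copies of the whole region would raise its neighbours alike, but the 24 genes within 5 Mb had a median of 0.41 (quartiles 0.1 and 0.67), which argues against it as the whole cause. Of the 24 genes 17 were higher and 2 lower, and their median exceeded 98.1% of 10192 windows of as many neighbouring genes, so a gain of the region as part of the cause stays open. A smaller segment stays open too: the median within 0.5 Mb was 1.01, from only 2 genes, BCAT1 (1.02) and ETFRF1, whose annotated position overlaps that of KRAS. The scaling of the libraries is argued against, since KRAS differed by 1.16 after total-sum scaling and by 1.08 after TMM, whereas a change in the regulation of KRAS, or in the mixture of cells in the pool, was not tested and may equally account for it.

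Airway secretory genes were lower in the resistant than in the naive pool, and some of them, such as CEACAM5, CEACAM6 and MUC5AC, were under 10 normalised read counts in every clone group, while others, such as ALDH3A1, were not. The shallow naive pool library is argued against as the cause of the difference between the pools, since the list's median was -4.48 without it. For genes found in the naive pool alone, cells of another kind on which AMG510 has no effect are argued against as the only source of them all. Such cells would change all these genes by the same factor. There were 22 genes with at least 100 normalised read counts in the naive pool and under 10 in every clone group. Their AMG510 effects in the naive pool had an interquartile range of 1.2, with 16 that rose, 1 that fell and 5 that did not pass. Such cells as the source of some of these genes stay open, since a range over all 22 cannot exclude a mixture of sources. Of the 22 genes 20 were under 10 in the resistant pool in vehicle, and TP53, which this line lacks, had 82.2 and 243.4 normalised read counts in the naive pool in vehicle and with AMG510 against 51.6 and 27.2 in the resistant pool. A subpopulation that responds to AMG510 and was lost under selection, of this line or of another kind, could give the pattern, and these bulk libraries do not show it directly.

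Cell cycle genes fell further with AMG510 in resistant than in naive clone 1. The scaling of the libraries is argued against, since the median of the G2-M list was -2.24 after total-sum scaling and -2.27 after TMM. A loss of depth is argued against, since the resistant clone 1 libraries with AMG510 had estimated depths of 20514822 to 22768768 reads, against 10316944 to 17064043 in naive clone 1 with AMG510. A stronger arrest of this resistant clone may explain it as a hypothesis, and cell counts were not used here.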

How the results depend on the processing

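The alternatives TMM, total-sum scaling (both also for camera), pseudocounts of 1 and 32, voom, the average of contrasts with a block, the handling of genes with no spread between clones, the pool signature between resistant and naive clones, the airway list without the shallowest library and the cell cycle lists of clone 2 without a naive library were chosen after the data had been seen.

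The 823 results of named genes followed here had all passed at an adjusted p below 0.05 in limma. Most were of genes picked by their fold change or p in that same fit. Their stability therefore says little about other called genes. Of 14230 values for these results under the alternatives, 14006 kept their direction and their side of the threshold, 223 were no longer called and 1 reversed. Of those lost, 144 came from leaving out a replicate, 24 from voom, 17 from a pseudocount of 1, 13 from a fit of 12 libraries, 11 from total-sum scaling, 6 from a pseudocount of 32, 4 from TMM, 2 from no filter, 1 from recomputed factors and 1 from a replicate block. The reversed value was the interaction of DHRS3 in the pool, 0.77 (adjusted p = 0.000984 in limma), which was -0.218 with a pseudocount of 32, and the cause was not tested. A count test on unnormalised reads was not run, since whole reads could not be recovered for most genes. Depth limits low genes, most of all in the shallowest naive pool library.

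The minimum fold, the pseudocount, voom and the test against a fold moved counts by more than 1.5 times. With a pseudocount of 1, resistant against naive cells gave 916, 381, 1834 and 2899 genes in vehicle in clone 1, clone 2, clone 3 and the pool, and 1705, 673 and 1675 in AMG510 in the clones. With a pseudocount of 32 the counts were 1228, 925, 1057 and 1322 for AMG510 in naive cells, 1271, 858, 901 and 1452 in resistant cells, 220, 86, 563 and 970 for resistance in vehicle, 571, 93, 567 and 1104 in AMG510, 338, 52, 321 and 880 for the interaction, 789 and 735 for AMG510 across clones, and 1576 and 2292 for differences among clones. Without a minimum fold they were 9895, 9152, 8688 and 10370, then 9716, 8485, 8153 and 10550, then 7618, 3752, 8942 and 10685, then 8945, 5700, 8581 and 9957, then 3449, 1915, 3426 and 7215, and 3252 and 3015 across clones, a direct result of the lower bar. voom gave 2090 and 2121 for AMG510 in resistant clone 2 and clone 3, 1119, 451 and 1814 for resistance in vehicle and 1832, 634 and 1706 in AMG510 in the clones. A test against a log2 fold change of 0.5 gave 25 and 423 for the interaction in clone 2 and clone 3. Without clone 1, AMG510 across naive clones gave 743, without clone 2 across resistant clones 699, and without clone 3 resistance in vehicle gave 11. The average of contrasts gave 192 for resistance and 97 for the interaction, and 192 and 99 with a block. List calls numbered 123 with an estimated correlation and 492 with fry.

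The medians of the pool signature with AMG510 kept their signs, and those between resistant and naive clones in vehicle were not run under the alternatives. For genes that rose they were 0.542 in resistant clone 3 with recomputed factors, 0.516 in resistant clone 3 and 0.6 in the resistant pool without a filter, and 0.508 in resistant clone 3 with TMM. With total-sum scaling they were 0.481 and 0.655 in naive clone 2 and clone 3 and 0.511, 0.492 and 0.617 in resistant clone 1, clone 3 and the pool. With a pseudocount of 1 they were 0.706 in naive clone 3 and 0.569, 0.546 and 0.61 in resistant clone 1, clone 3 and the pool. With 32 they were 0.836, 0.68 and 0.813 in naive and 0.681, 0.604, 0.649 and 0.818 in resistant cells. Without a minimum fold they were 0.315, 0.222 and 0.27, and 0.258, 0.249, 0.241 and 0.294. For genes that fell TMM gave -1.232 and -0.972 in resistant clone 1 and clone 2, and total-sum scaling gave -1.195 and -1.011 in naive and -1.268 and -0.978 in resistant clone 1 and clone 2. A pseudocount of 1 gave -0.975 in naive clone 2 and -1.233 and -1.044 in resistant clone 1 and clone 3. A pseudocount of 32 gave -1.192, -1.036 and -1.157 in naive and -1.419, -1.056 and -1.098 in resistant clones. No minimum fold gave -0.379, -0.284 and -0.345, and -0.337, -0.295, -0.292 and -0.387. The resemblance of siblings was 0.518 without a filter, 0.64 over genes that differed among naive clones, 0.455 in AMG510 and 0.476 as Spearman's rho. The causes were not tested.

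With total-sum scaling the median log2 fold change of all genes for resistance in AMG510 was -0.112 in clone 1 and 0.101 in clone 2, against -0.02 and 0.01 with the deposited scaling. Recomputed factors, no filter, the stricter filter, TMM, total-sum scaling and the fit of 12 libraries moved no count of genes by more than 1.5 times. The balance of directions turned in some settings: with no minimum fold 12 comparisons had more genes in the other direction than before (AMG510 in all 8 cultures, resistance in vehicle in clone 1 and in AMG510 in clone 2 and clone 3, and the interaction in the pool), and 1 each had with total-sum scaling (resistance in vehicle, clone 1), a pseudocount of 1 (AMG510 in the naive pool), a pseudocount of 32 (resistance in AMG510, clone 2), voom (the interaction, clone 3) and the test against a fold (the interaction, clone 2).

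A block for the replicate number gave 1935, 1583, 1668 and 2223 genes for AMG510 in naive clone 1, clone 2, clone 3 and the pool, 1953, 1357, 1407 and 2278 in resistant cells, 509, 225, 1115 and 1847 for resistance in vehicle, 1096, 319, 1047 and 1879 in AMG510, 716, 188, 690 and 1808 for the interaction, 3161 and 4191 for differences among naive and among resistant clones, 265 list calls, and 1355 and 1282 for AMG510 across naive and resistant clones as an average of contrasts. Libraries of the same replicate number were not treated as paired: of 72 such pairs 12 had a residual correlation above 0.1, and the median was 0.049 against -0.021 for other pairs. Most of the 12 were pairs of pool libraries. In the pool same-numbered pairs ranged from -0.137 to 0.338 and other pairs from -0.384 to 0.332, so its libraries varied together in ways that the replicate number did not follow.

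Leaving out each replicate in turn gave these lowest and highest values, in the order clone 1, clone 2, clone 3 and pool, and moved no count by more than 1.5 times. AMG510 in naive cells gave 1917 to 2012, 1533 to 1701, 1655 to 1739 and 2121 to 2509, and in resistant cells 1955 to 2005, 1353 to 1385, 1412 to 1445 and 2245 to 2332. Resistance gave 515 to 559, 211 to 243, 1105 to 1171 and 1669 to 2181 in vehicle, and 1066 to 1193, 324 to 357, 1065 to 1110 and 1881 to 1975 in AMG510. The interaction gave 682 to 778, 135 to 223, 676 to 717 and 1594 to 2084. Across clones AMG510 gave 1217 to 1263 in naive and 1102 to 1126 in resistant cells, and resistance and the interaction gave 0 to 0. Differences among clones were 2964 to 3051 and 3975 to 4101. The pool signature's rising genes had medians of 0.557 to 0.78, 0.423 to 0.63 and 0.564 to 0.79 in naive clones, and 0.47 to 0.663, 0.422 to 0.569, 0.425 to 0.58 and 0.473 to 0.68 in resistant cells. Its falling genes had -1.164 to -1.046, -0.964 to -0.859 and -1.128 to -1.027, and -1.236 to -1.083, -0.971 to -0.868, -1.007 to -0.919 and -1.168 to -1.04. Siblings resembled each other at 0.511 to 0.525. The lowest pool counts for AMG510 in naive cells, resistance in vehicle and the interaction came without the shallowest library. In the resistant pool, replicate 1 with vehicle and replicate 2 with AMG510 each differed more from the others of their group than these did from each other. The ranges above include the fits without each of these libraries.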

Other observations

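No test in this part was chosen after its result had been seen, and which results to print was chosen then.

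Survival and growth-factor genes answered AMG510 in naive cells mostly without their whole lists moving. BMF, which promotes cell death, rose by 4.48, 3.42, 2.04 and 2.80 on the log2 scale in clone 1, clone 2, clone 3 and the pool. The apoptosis list had medians of 0.02, 0.04, 0.15 and 0.15 and passed in camera in the pool alone, at adjusted p = 0.0653 with an estimated correlation. The receptor and ligand list did not pass (medians 0.30, 0.07, 0.04 and 0.20), though IGF2 and FGFR2 rose and FGFR1 fell in every lineage. The RAS and RAF-MEK-ERK genes did not pass either (medians -0.03, 0.05, 0.08 and -0.14). CDK inhibitors and p53 targets were higher (medians 0.43, 0.29, 0.40 and 0.33), led by CDKN1A and GADD45B, at adjusted p = 0.0947, 0.123, 0.0313 and 0.05 with an estimated correlation. YAP-TEAD targets were higher (medians 0.24, 0.26, 0.21 and 0.49), at adjusted p = 0.185, 0.197, 0.294 and 0.0973 with an estimated correlation. In the pool 13 of 21 apoptosis genes rose less or fell further in resistant than in naive cells (13 adjusted over the list alone; median -0.43), led by PMAIP1, MCL1, BBC3 and BCL2L1. In clone 1 13 of 19 TGF-beta and BMP targets did (15 adjusted over the list alone; median -0.45), led by CCN2, PMEPA1, BMP2 and LTBP2.

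Some lists of metabolism and cell identity moved with AMG510 in naive cells. Fatty acid synthesis was lower (medians -0.43, -0.36, -0.18 and -0.36 in clone 1, clone 2, clone 3 and the pool), led by ELOVL6, SCD and SREBF1, at adjusted p = 0.0379, 0.065, 0.185 and 0.0107 with an estimated correlation. Glycolysis and hypoxia genes were lower in the pool (median -0.30), at adjusted p = 0.128 with an estimated correlation. Drug efflux and aldehyde dehydrogenase genes were higher in clone 1 and the pool (medians 0.40 and 0.73), led by ABCC1 and ALDH1A3 over the 4 lineages. In vehicle 10 of 18 were lower in the resistant than in the naive pool (10 adjusted over the list alone; median -0.48), led by ALDH3A1, CYP1B1, ALDH3B1 and UGT1A6. FOXO and PI3K feedback genes were higher with AMG510 in naive clone 1 (median 0.38), at adjusted p = 0.132 with an estimated correlation, and 13 of 22 were lower in the resistant pool in vehicle (14 adjusted over the list alone; median -0.50). Alveolar genes rose with AMG510 in the resistant pool, 8 of 11 (8 adjusted over the list alone; median 0.60), led by CLIC5, LPCAT1, LAMP3 and CAV2. Cytosolic ribosomal proteins were higher with AMG510 in naive clone 1, clone 2 and the pool (medians 0.31, 0.23 and 0.10), at adjusted p = 0.286, 0.441 and 0.64 with an estimated correlation. In vehicle 29 of 30 of them were higher in resistant than in naive clone 1 (29 adjusted over the list alone; median 0.53) and 26 were lower in clone 3 and 26 in the pool (27 and 26 adjusted over the list alone; medians -0.42 and -0.33), at adjusted p = 0.0552, 0.424 and 0.281 with an estimated correlation. Wnt and Notch targets (medians -0.14, -0.18, -0.31 and -0.36) and the 5 neuroendocrine genes tested (medians -0.16, 0.15, 0.19 and -0.06) did not pass in camera with AMG510 in naive cells.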
